A study of Mus musculus with 10 samples.

How the data were processed

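RNA was extracted from hearts of 8-week-old C57BL/6 mice and sequenced after preparation with an Illumina TruSeq RNA kit, per the labels' protocols. The labels give 10 libraries, 5 from mice injected with saline and 5 from mice 24 h after lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria that is injected to model sepsis. Each library is numbered as a mouse of its own, and no batch, sex or dose is given in the sources used here.

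The authors deposited a table of read counts per gene for 54532 Ensembl gene identifiers, with 1 column of counts per library. The submitters' processing notes name Bowtie 0.12.2 and the mm9 build, with no role or order. The counting tool, the annotation release and whether counting used the strand are not given in the sources used here. The gene coordinates in the count table were compared with GENCODE M21, an annotation of the GRCm38 build. Of the 54532 identifiers, 54409 were found there and 53499 had the same start and end, so coordinates are given as GRCm38, although the notes name mm9. Without a stated strand, reads of a gene and of an antisense or overlapping gene cannot be told apart, and reads of near-identical genes may have been split between copies.

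The same table holds the authors' FPKM columns (reads per kilobase of gene length, scaled to library size). Within each library the ratio of counts to FPKM times gene length was constant, and the scaled library size was between 0.776 and 1.09 times the total count. FPKM values were used in no test. Further tables deposited by the authors hold FPKM of 6271 and 40 genes. In both, the 5 columns for LPS are named for 3 h, and in every gene they equal the FPKM columns named for 24 h in the count table. The 10 columns so named in these tables were not used here. The groups follow the labels, which give 24 h, and the files alone do not tell which time is right. A deposited table of Reactome terms holds the authors' p-value and adjusted p-value per term, with the numbers of differential genes up and down. The tool and the threshold behind it are not given in the sources used here, and its values are quoted as the authors' own.

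Counts were analysed with R 4.3.3 and edgeR 4.0.16. Genes were kept by the filterByExpr function with its defaults (minimum count 10 and minimum total count 15), which left 13864 of 54532 genes. Libraries were scaled by TMM factors. LPS was compared with saline by edgeR's quasi-likelihood F-test with robust dispersion estimates, and p-values were adjusted by the Benjamini-Hochberg method over the tested genes with a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. CPM denote counts scaled by the effective library size (total count times TMM factor). Values are given as mean ± SD over the 5 libraries of a group unless stated otherwise. "Rose" and "fell" are used of genes past the threshold.

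Before the data were examined, 32 gene lists were fixed, 22 of pathways and 10 of cell types. Each was tested with camera on limma 3.58.1 voom values with a preset inter-gene correlation of 0.01, two-sided, adjusted over the 32 lists. Members were also counted with p-values adjusted over the list alone. The rule for named genes was fixed at the same time. It takes Tlr4, Traf6, Tfeb, Tfe3, Sqstm1, Map1lc3b, Becn1 and Lamp1. It takes the 5 highest and 5 lowest log2 fold changes among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups. From each list it takes the 3 members with the largest change in the more frequent direction and the 1 with the largest change in the other, or the 2 with the highest mean CPM where no member passed. A gene that the rule takes is not reported here. A few other genes are named to illustrate a count and were chosen after their values were seen. Principal components were computed on log2 CPM (prior count 2) of the 1000 most variable genes. Measures per library were compared by an exact permutation test, two-sided, over the 252 assignments of 5 and 5 libraries, adjusted over 7 measures.

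The test was tried on simulated data with the real libraries' means and sizes and 13864 genes. Of 50 genes changed by 1.5-fold, 11 were recovered. Of 50 genes each, 33 were recovered at 2-fold, 48 at 4-fold and 50 at 8-fold, and 6 of 148 calls were false. Only these genes were changed, a far smaller share than the 39.9% of tested genes that differed in the data. Fewer changed genes make the adjusted threshold stricter, so the recovered numbers may understate what the test finds in the data. The total count per library was between 14607969 and 17012372 over all genes. Counting intervals of ratios are exact binomial ones and cover counting error only, and a floor of 3 reads over a group stands for a count of 0.

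The alternatives were RLE, upper quartile and total count scaling, scaling without the 20 most abundant genes, no filter on low counts, a filter of 1 CPM in 5 libraries, DESeq2 1.42.0, limma voom, a threshold of 0.01, the replicate number as a block, and each of the 10 libraries left out in turn. For lists they were an estimated correlation, the fry rotation test and lists without shared genes. After the data were seen, fits without saline replicates 2 and 5 together, and an estimated correlation without saline replicate 5, were added. The 40668 genes under the filter were not analysed here except without the filter.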

Results

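Heart transcriptomes of 5 saline-injected mice and 5 mice 24 h after LPS were compared, to find how the heart's mRNA differs in endotoxin-induced sepsis, with the study's title pointing to the LPS receptor TLR4, the ubiquitin ligase TRAF6, the transcription factor TFEB and autophagy. The total count was 16210000 ± 542700 (SD, n = 5) in saline libraries and 15260000 ± 1016000 (SD, n = 5) in LPS libraries, a difference within the spread between libraries (exact permutation test, two-sided, p = 0.119, adjusted p = 0.167 over 7 measures). Mitochondrially encoded genes took 26.4% ± 1.48 of counts in saline and 26.8% ± 3.51 in LPS libraries (exact p = 0.810, n = 5 per group). The TMM factor was 1.10 ± 0.0602 in saline and 0.911 ± 0.0554 in LPS libraries (exact p = 0.00794, adjusted p = 0.0185), and 19730 ± 208 and 19160 ± 317 genes had a read (exact p = 0.0159, adjusted p = 0.0278), differences beyond the spread between libraries.

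The first principal component of the 1000 most variable genes held 91.0% of their variance and separated the groups. LPS libraries lay between 43.7 and 55.0 and saline replicates 1 to 4 between -67.0 and -55.1. Saline replicate 5 lay between the groups, at -0.563. Interferon-stimulated genes of the fixed list took 0.0711%, 0.205%, 0.0767% and 0.0748% of counts in saline replicates 1 to 4, 1.04% in saline replicate 5 and 1.77% to 3.21% in LPS libraries. Since saline replicate 5 moves with the inflammatory genes, values without it are given beside the results it changes.

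**Figure D1:**
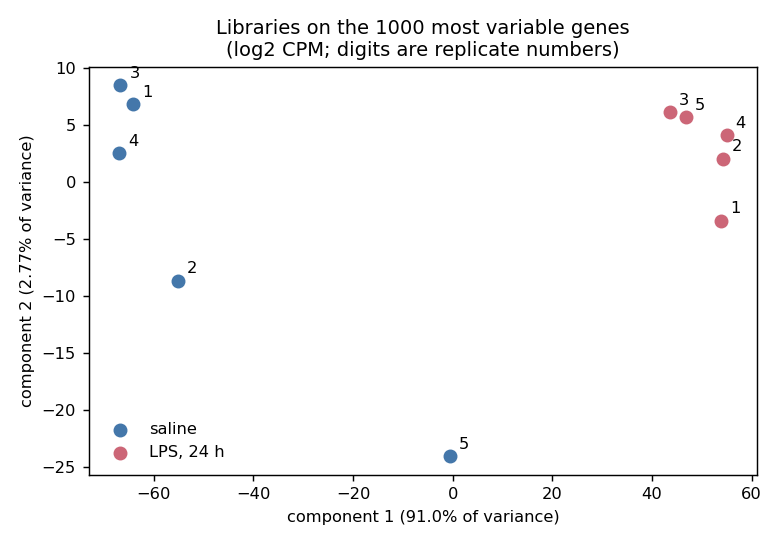
Each point is a heart library placed by its first (horizontal) and second (vertical) principal component of log2 CPM of the 1000 most variable genes, with the share of variance on each axis; digits are replicate numbers. LPS libraries lie between 43.7 and 55.0 on component 1, saline replicates 1 to 4 between -67.0 and -55.1, and saline replicate 5 at -0.563.

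LPS hearts differed from saline hearts in 5533 of 13864 tested genes, 39.9%, by edgeR's quasi-likelihood test. Of these, 2617 rose and 2916 fell, and 1246 rose and 1082 fell at least 2-fold. In 1923 rising and 1908 falling genes the 5 LPS libraries did not overlap the 5 saline libraries, which chance gives for 0.79% of genes. Without saline replicate 5, 2967 genes rose and 3241 fell of 14123 tested, and 2561 of the 2617 rising and 2838 of the 2916 falling genes kept their call. Rising genes were 47.3% of the changed genes with TMM scaling, 50.7% with RLE, 31.1% with upper quartile and 22.9% with total count scaling. Upper quartile scaling shifted the median log2 fold change of all genes by -0.16 and total count scaling by -0.27.

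Among genes with a mean of at least 5 CPM and no overlap between the groups, the largest rises, with saline replicate 5 included, belonged to Cxcl5, a neutrophil-attracting chemokine, Csf2, which encodes the growth factor GM-CSF, Ubd, a ubiquitin-like protein, and the predicted genes Gm37975 and Gm10851. Cxcl5 was at 0.749 ± 0.712 CPM in saline and 271 ± 15.2 CPM in LPS hearts (SD, n = 5 per group), a log2 fold change of 8.51 ± 0.47 (SE, adjusted p = 1.49e-06, edgeR), and 9.28 without saline replicate 5. Csf2 had 3 reads in saline, all in saline replicate 4, and 708 in LPS libraries, a ratio of 302 with a 95% counting interval of 103 to 1470. Ubd, Gm37975 and Gm10851 had 8, 12 and 28 saline reads, all in saline replicate 5. Against saline replicates 1 to 4, taken at a floor of 3 reads over the group, they were at least 271-fold, 444-fold and 813-fold higher. Gm37975 and Gm10851 both lie inside Pfkfb3 (GRCm38 chromosome 2, 11471433 to 11554077), Gm10851 on the other strand, so their reads may include reads of Pfkfb3.

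Among genes chosen by the same limits, the largest falls belonged to Gm12002, D630003M21Rik, the kinesin Kif26a, Kcnj8, which encodes a pore subunit of vascular ATP-sensitive potassium channels, and Palm, which encodes the membrane protein paralemmin. Kcnj8 fell from 47.5 ± 11.8 to 1.83 ± 0.416 CPM (log2 fold change -4.70 ± 0.22 SE, adjusted p = 2.15e-08, edgeR, n = 5 per group). Palm fell from 44.3 ± 14.5 to 2.02 ± 0.665 CPM and Kif26a from 24.7 ± 10.3 to 0.874 ± 0.29 CPM. The log2 fold changes of Gm12002 and D630003M21Rik were -6.01 ± 0.58 and -5.62 ± 0.50 (SE). Gm12002 lies inside Cobl (chromosome 11, 12236608 to 12464960) on the other strand, and whether counting used the strand is not given in the sources used here. Of the 127 genes named by rule, 29 overlap another gene with at least 100 reads, among them Map1lc3b (Zcchc14), Lamp1 (Grtp1), Myd88 (Acaa1a) and Irak3 (Tmbim4), each on the other strand. Reads in the shared stretches carry the same uncertainty, but the overlaps differ in extent. That of Map1lc3b is short, since it ends at 121598760 on chromosome 8 and Zcchc14 starts at 121598703.

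Genes of TLR4 signalling rose as a group, with 19 rising and 2 falling of 32 tested (camera adjusted p = 8.02e-06, and adjusted p = 0.503 with an estimated correlation). Counted with p-values adjusted over the list alone, 21 rose and 2 fell. Tlr4 itself (ENSMUSG00000039005, chromosome 4, 66827584 to 66930284) rose from 17.2 ± 2.1 to 31.2 ± 5.32 CPM (SD, n = 5 per group), a log2 fold change of 0.86 ± 0.13 (SE, adjusted p = 0.000131, edgeR). Traf6 (ENSMUSG00000027164, chromosome 2, 101678429 to 101701669) was at 19.9 ± 4.73 CPM in saline and 26.3 ± 0.971 CPM in LPS hearts, a log2 fold change of 0.40 ± 0.13 (adjusted p = 0.0267). Saline replicate 5, at 28.2 CPM, lay above the 5 LPS libraries, and without it the log2 fold change of Traf6 was 0.57 (edgeR adjusted p = 0.000186). The call of Traf6 was lost without saline replicate 1, 2, 3 or 4 (adjusted p up to 0.0754), in fits that all kept saline replicate 5. Tnfaip3, an inhibitor of NF-kappaB, Myd88, the adaptor of most Toll-like receptors, and Irak3, an inhibitory kinase of the pathway, had the largest rises, with log2 fold changes of 3.93 ± 1.13, 2.69 ± 0.49 and 2.59 ± 0.39 (SE). With saline replicate 5 left out they were 6.18, 3.39 and 3.02, and the call of Tnfaip3 was lost without saline replicate 2 (adjusted p = 0.0558). Ticam1, the adaptor of the MyD88-independent arm, fell (-0.59 ± 0.15).

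With an estimated inter-gene correlation 0 of 32 lists passed the threshold with camera, 1 had an unadjusted p under 0.05, and 14 passed with the fry rotation test, which asks whether a list's genes move on balance and does not compare them with other genes. With saline replicate 5 left out the TLR4 list had adjusted p = 0.0104, the cytokine list 0.0371, the acute-phase list 0.00494 and the interferon list 0.303 with an estimated correlation.

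Inflammatory cytokines and adhesion molecules rose in 23 of 30 tested members and fell in 0 (camera adjusted p = 5e-16, and adjusted p = 0.503 with an estimated correlation), and 26 rose when adjusted over the list alone. Besides Cxcl5 the largest rises were in Csf3, the growth factor of neutrophils, with 1.03 ± 2.31 CPM in saline and 106 ± 19.7 CPM in LPS hearts (log2 fold change 6.71 ± 1.15 SE, adjusted p = 0.00191), and in Il6, the inducer of the acute-phase response, with 2.21 ± 4.91 and 219 ± 135 CPM (6.65 ± 1.57, adjusted p = 0.00999). Nearly all saline reads of these genes came from saline replicate 5, with 87 of 87 for Csf3 and 185 of 186 for Il6. Against saline replicates 1 to 4, Csf3 was at least 2560-fold higher in LPS hearts (floor of 3 reads over the group). Without saline replicate 5, 31 of 31 tested members rose.

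Interferon-stimulated genes rose in 37 of 44 members and fell in 0 (camera adjusted p = 6.1e-20, and adjusted p = 0.503 with an estimated correlation), and 42 rose when adjusted over the list alone. Cxcl11, the chemokine gene Cxcl9 and the RNA sensor gene Dhx58 changed most, with log2 fold changes of 5.58 ± 1.37, 4.48 ± 1.24 and 4.10 ± 0.77 (SE). Cxcl9 was at 63.9 ± 114 CPM in saline and 1423 ± 658 CPM in LPS hearts, and saline replicate 5 alone was at 268 CPM. Without saline replicate 2, 23 members rose. Without saline replicate 5, 44 of 44 members rose and the log2 fold changes of Cxcl9 and Dhx58 were 6.78 and 5.18. Cxcl11 had 1 of its 194 saline reads in replicates 1 to 4, and its ratio of LPS to these libraries was 7620 with a 95% counting interval of 1370 to 301000.

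Acute-phase and antimicrobial genes rose in 17 of 20 tested members and fell in 0 (camera adjusted p = 8.35e-12, and adjusted p = 0.503 with an estimated correlation), and 19 rose when adjusted over the list alone. The pattern recognition molecule Ptx3 went from 13.6 ± 28.6 to 1020 ± 356 CPM, the iron-binding lipocalin Lcn2 from 7.71 ± 10.3 to 407 ± 105 CPM and serum amyloid Saa3 from 2.55 ± 5.65 to 107 ± 58.6 CPM (SD, n = 5 per group; edgeR adjusted p = 0.0193, 0.000951 and 0.0146). Saline replicate 5 was at 64.7, 26.1 and 12.7 CPM. Without it, 20 of 20 members rose, and the log2 fold changes of Ptx3 and Lcn2 went from 6.24 and 5.73 to 10.36 and 7.04. Saa3 had 2 of its 215 saline reads in replicates 1 to 4.

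Genes of the autophagy machinery went both ways, as did all tested genes, of which 39.9% passed the threshold (2617 rose and 2916 fell). Of 37 core genes 4 rose and 5 fell (camera adjusted p = 0.574), or 2 and 4 when adjusted over the list alone. The number rising was 2 without saline replicate 1, 3 or 4 or LPS replicate 4, and the number falling was 3 without LPS replicate 2 or 4. Map1lc3b, which encodes the autophagosome protein LC3B, rose from 214 ± 15.2 to 254 ± 22.8 CPM (log2 fold change 0.25 ± 0.09 SE, adjusted p = 0.0398, edgeR, n = 5 per group), a call lost without saline replicate 1, 2, 3 or 4 or LPS replicate 3 or 4 (adjusted p up to 0.0784). With total count scaling its log2 fold change was -0.03. Becn1, a subunit of the kinase complex that starts autophagosomes, had a log2 fold change of 0.22 ± 0.09 (adjusted p = 0.0705, and 0.0345 without LPS replicate 3). Vmp1, an autophagosome formation protein, rose by 0.56 ± 0.10, and the LC3-processing proteases Atg4c and Atg4a fell, with log2 fold changes of -0.80 ± 0.20 and -0.53 ± 0.11. Epg5, a tether for autophagosomes, fell (-0.40 ± 0.12), a call lost without LPS replicate 2 or 4 (adjusted p up to 0.0531). Of 18 autophagy and mitophagy receptors 3 rose and 3 fell (adjusted p = 0.810), with the same counts adjusted over the list alone. Sqstm1, the cargo receptor p62, was at 270 ± 31.6 CPM in saline and 298 ± 45 CPM in LPS hearts (adjusted p = 0.342). The mitophagy receptors Bnip3 and Bcl2l13 rose by 0.51 ± 0.10 and 0.32 ± 0.09, Tax1bp1 rose by 0.43 ± 0.13 (adjusted p = 0.0505 without saline replicate 3), and Bnip3l fell (-0.80 ± 0.08, adjusted p = 4.92e-06).

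Lysosomal genes of the CLEAR network, the set that TFEB is known to drive, also split, with 9 rising and 10 falling of 46 (camera adjusted p = 0.932) and the same counts adjusted over the list alone. The share that passed was near the 39.9% of all tested genes. The median log2 fold change of the lysosomal list was 0.02, and -0.25 with total count scaling, while its mean was -0.04. Lamp1 was at 421 ± 20.4 CPM in saline and 420 ± 18.3 CPM in LPS hearts (adjusted p = 0.983), while Lamp2, another lysosomal membrane protein, rose from 189 ± 26.7 to 303 ± 38 CPM (log2 fold change 0.68 ± 0.11 SE, adjusted p = 0.000317, edgeR, n = 5 per group). The lysosomal hydrolases Sgsh and Gusb fell (-0.95 ± 0.22 and -0.89 ± 0.19), as did Flcn, a regulator of TFEB at the lysosome (-0.76 ± 0.10).

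Tfeb (ENSMUSG00000023990, chromosome 17, 47737030 to 47792419) fell from 23.2 ± 3.3 to 15.2 ± 3.05 CPM (SD, n = 5 per group), with no overlap between the groups and a log2 fold change of -0.61 ± 0.15 (SE, adjusted p = 0.00442, edgeR). Its relative Tfe3 was at 19.1 ± 3.11 CPM in saline and 15.7 ± 2.89 CPM in LPS hearts (adjusted p = 0.135). Of 25 MiT transcription factors and mTORC1 genes 3 rose and 5 fell (camera adjusted p = 0.845), or 2 and 4 when adjusted over the list alone, and 1 rose without saline replicate 2 or 3. Ddit4, an inhibitor of mTORC1, Zkscan3, a repressor of autophagy genes, and Mitf fell (-1.37 ± 0.34, -0.79 ± 0.12 and -0.62 ± 0.15). Tfec, the family's member of macrophages, rose (2.22 ± 0.64, and 3.53 without saline replicate 5), a call lost without saline replicate 2 (adjusted p = 0.0522).

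**Figure D2:**
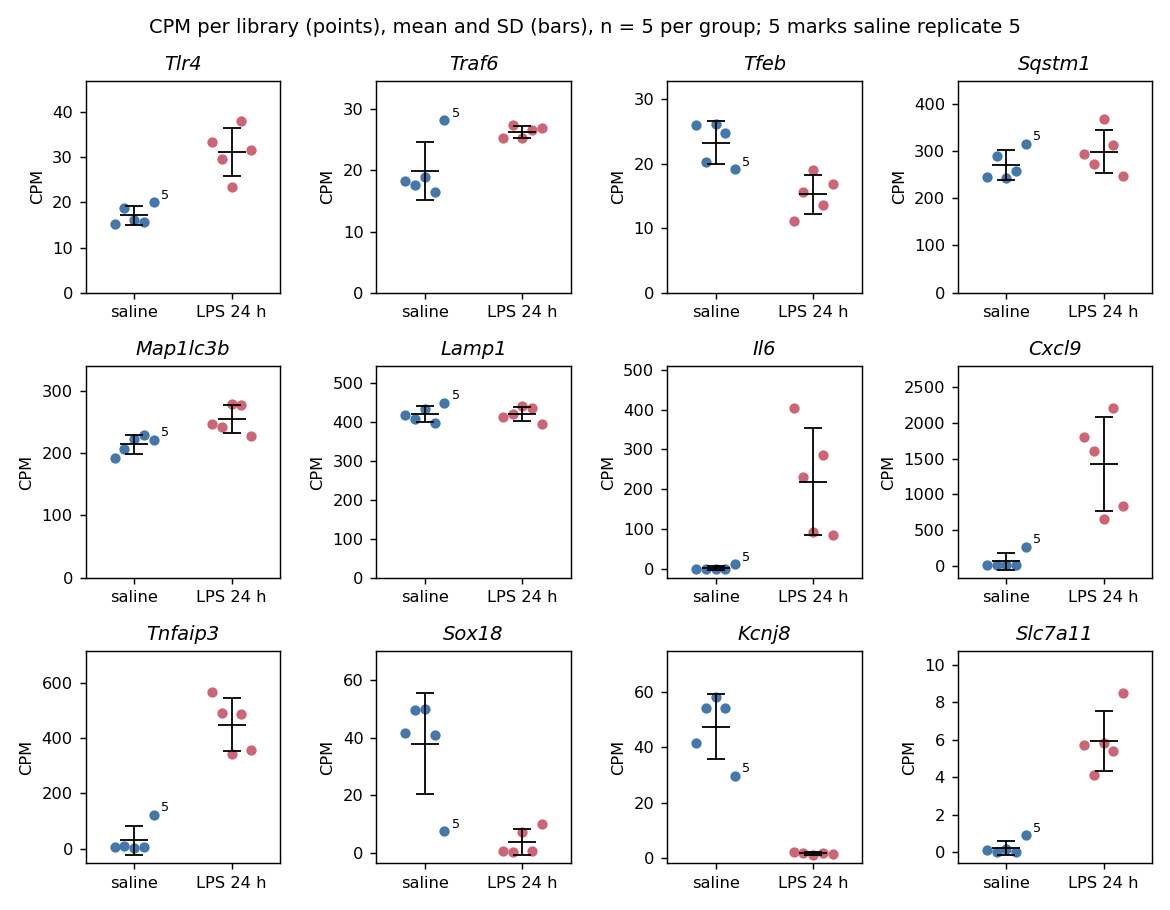
CPM (vertical axes, which include 0) of 12 named genes in each library (points) of the saline and LPS groups, with the mean and SD of 5 libraries (bars); the digit 5 marks saline replicate 5. Tlr4 was at 17.2 CPM in saline and 31.2 CPM in LPS hearts, Tfeb at 23.2 and 15.2 CPM and Lamp1 at 421 and 420 CPM, and saline replicate 5 was at 28.2 CPM for Traf6.

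Metabolic lists had median log2 fold changes of at most 0.19 with TMM scaling and all libraries, but several calls depended on single libraries. Without LPS replicate 5 the respiratory chain, tricarboxylic acid cycle, fatty acid and glycolysis lists passed upward (camera adjusted p from 0.00107 to 0.00894). The list of metabolic regulators did not (0.597). An estimated correlation was not tried without LPS replicate 5. Of 73 respiratory chain and ATP synthase genes 0 passed the threshold with edgeR and 3 with DESeq2, and 6 had an unadjusted p under 0.05, all upward (camera adjusted p = 0.637). The count was 0 adjusted over the list alone, although 4 rose without saline replicate 5 and 15 without LPS replicate 5, where the list passed (adjusted p = 0.00602; 0.944 with an estimated correlation and all libraries). Without LPS replicate 1, 0 rose and 2 fell, and without LPS replicate 3, 1 rose. Atp5b and Atp5a1, its most abundant members, had log2 fold changes of 0.09 ± 0.09 and 0.20 ± 0.09 (SE, adjusted p = 0.462 and 0.0931; 0.00517 for Atp5a1 without LPS replicate 5). Of 24 genes of the tricarboxylic acid cycle and pyruvate 4 rose and 1 fell (camera adjusted p = 0.0156, and 0.781 with an estimated correlation), or 1 and 1 adjusted over the list alone, with a median log2 fold change of 0.19 that became -0.09 with total count scaling. Pdk1, an inhibitor of pyruvate dehydrogenase, rose by 0.32 ± 0.08 and Pdp1, its activating phosphatase, fell (-0.60 ± 0.12). The pyruvate carrier subunit Mpc1 (0.33 ± 0.13) and Pdha1 (0.31 ± 0.11) rose, calls lost without several of the single libraries (adjusted p up to 0.103 and 0.079, Mpc1 also without saline replicate 5). In this list 9 members rose without saline replicate 5 or LPS replicate 5, 2 without saline replicate 2 or 3 or LPS replicate 4, and 1 without saline replicate 4.

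Of 32 genes of fatty acid uptake and oxidation 4 rose and 1 fell (camera adjusted p = 0.0766), or 2 and 1 adjusted over the list alone, with a median of 0.16 that became -0.12 with total count scaling. The lipase Pnpla2, the transporter Slc27a1 and Cpt2 rose by 0.44 ± 0.10, 0.34 ± 0.11 and 0.32 ± 0.09, and Cpt1a, the carnitine palmitoyltransferase form of liver, fell (-0.57 ± 0.11). Slc27a1 lost its call without saline replicate 3 or 4 (adjusted p up to 0.064). Without saline replicate 5, LPS replicate 4 or LPS replicate 5 the list passed (adjusted p = 0.0483, 0.0469 and 0.00894; with an estimated correlation adjusted p = 0.715 without saline replicate 5 and 0.781 with all libraries), and 7 members rose without saline replicate 5, 11 without LPS replicate 5 and 2 without saline replicate 3 or 4, while 2 fell without saline replicate 1 or LPS replicate 1. Of 24 glycolysis genes 4 rose and 0 fell (camera adjusted p = 0.0625), 3 adjusted over the list alone, with a median of 0.12 that became -0.15 with total count scaling. The glucose transporter Slc2a1, Pfkp and the hexokinase Hk2 rose by 0.93 ± 0.13, 0.80 ± 0.08 and 0.43 ± 0.11. This list passed without saline replicate 1 or 5 or LPS replicate 2 or 5 (adjusted p = 0.0357, 0.0448, 0.0415 and 0.00729; with an estimated correlation adjusted p = 0.661 without saline replicate 5 and 0.767 with all libraries), and 7 members rose without LPS replicate 5. Of 22 regulators of mitochondrial and lipid metabolism 1 rose and 5 fell (camera adjusted p = 0.574), the same adjusted over the list alone, and 2 rose without saline replicate 5 or LPS replicate 3; their median was 0.06, and -0.22 with total count scaling, and their mean -0.09. Ppargc1b, a coactivator of mitochondrial genes, fell from 17.1 ± 4.2 to 6.02 ± 1.63 CPM (-1.51 ± 0.20), the receptors Thra and Rxra fell (-0.60 ± 0.09 and -0.53 ± 0.10), and Ppard rose (0.48 ± 0.14).

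Sarcomere genes passed the threshold in 3 of 27 members, all rising (camera adjusted p = 0.168), 1 of them adjusted over the list alone, with a median of 0.11 that became -0.15 with total count scaling. Xirp1, an intercalated disc protein, rose from 150 ± 22.2 to 309 ± 76.9 CPM (1.04 ± 0.16). Ankrd1 and Mybpc3 rose by 0.48 ± 0.17 and 0.25 ± 0.09, calls lost without several single libraries, among them saline replicates 2, 3 and 4 (adjusted p up to 0.0799 and 0.0854). With total count scaling Mybpc3 had a log2 fold change of -0.02. The list passed without LPS replicate 5 (adjusted p = 0.0494; 0.781 with an estimated correlation and all libraries), and 5 members rose without saline replicate 5 and 1 without saline replicate 2 or 3. Of 39 calcium handling and ion channel genes 6 rose and 6 fell (camera adjusted p = 0.232), the same adjusted over the list alone, and 10 rose without saline replicate 5. Gja5, a gap junction protein of atria, conduction tissue and arterial endothelium, fell from 11.8 ± 3.04 to 2.04 ± 0.359 CPM (-2.53 ± 0.22), while the sodium pump subunit Atp1b1 (0.49 ± 0.11) rose. Kcna5 rose by 0.55 ± 0.18, a call lost without saline replicate 1, 3 or 4 or LPS replicate 3 or 5 (adjusted p up to 0.0642).

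Of 18 fetal and wall-stress genes 4 rose and 2 fell (camera adjusted p = 0.087), the same adjusted over the list alone. Rcan1, an inhibitor of calcineurin, rose from 88.7 ± 13.2 to 589 ± 92.2 CPM (2.73 ± 0.13 SE, adjusted p = 1.9e-08, edgeR, n = 5 per group). The stress-induced transcription factors Atf3 and Egr1 rose by 2.52 ± 0.78 and 1.96 ± 0.62 and the chaperone gene Hspa1a, a near copy of Hspa1b whose reads could be shared with it, fell (-1.31 ± 0.44). These 3 calls were lost without single libraries (adjusted p up to 0.0751, 0.0823 and 0.0903), Hspa1a also without saline replicate 5, while Atf3 had 3.86 without that library. Without saline replicate 4 or LPS replicate 1, 2 or 4 the list had 2 rising members, and without saline replicate 2 or any LPS replicate from 2 to 5 it had 1 falling.

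Ubiquitin ligase and proteasome genes rose in 17 and fell in 2 of 44 members (camera adjusted p = 0.00158, and 0.62 with an estimated correlation), the same adjusted over the list alone. Their median log2 fold change was 0.19, and -0.07 with total count scaling. The proteasome activator genes Psme2 and Psme1 rose by 1.12 ± 0.21 and 0.76 ± 0.12. The muscle ubiquitin ligase gene Fbxo32 rose from 124 ± 32 to 226 ± 33 CPM (0.86 ± 0.16) and Fbxo40 fell (-0.58 ± 0.09). Cell death genes rose in 17 and fell in 5 of 32 (camera adjusted p = 0.000361, and 0.503 with an estimated correlation), or 20 and 6 adjusted over the list alone. Bcl2a1a, which protects cells from death, Mlkl, the executor of necroptosis, and Casp4, a sensor of intracellular LPS, rose by 4.02 ± 0.63, 3.90 ± 0.46 and 3.54 ± 1.03 (5.88, 4.47 and 5.68 without saline replicate 5), and the anti-apoptotic Bcl2 fell (-1.77 ± 0.18). Casp4 lost its call without saline replicate 1, 2, 3 or 4 (adjusted p up to 0.0562). The list thus held rising members of opposite known action.

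Of 30 antioxidant and iron genes 13 rose and 2 fell (camera adjusted p = 0.0132, and 0.556 with an estimated correlation), the same adjusted over the list alone; the median of 0.17 became -0.11 with total count scaling. The cystine transporter Slc7a11, the iron hormone hepcidin gene Hamp and the haem oxygenase Hmox1 rose by 4.66 ± 0.62, 4.22 ± 0.72 and 2.41 ± 0.27 (6.27, 5.75 and 2.43 without saline replicate 5). The ferritin subunit Ftl1 fell (-0.66 ± 0.20), a call lost without saline replicate 2 or LPS replicate 4 or 5 (adjusted p up to 0.0614). Of 28 glucocorticoid-responsive and clock genes 11 rose and 6 fell (camera adjusted p = 0.0766, and 0.0385 and 0.0483 without saline replicate 4 or 5; with an estimated correlation adjusted p = 0.503 with all libraries and 0.634 without saline replicate 5), the same adjusted over the list alone, with a median of 0.24 that became -0.04 with total count scaling. Angptl4, Cebpd and Cebpb rose by 2.35 ± 0.54, 2.22 ± 0.60 and 1.82 ± 0.23, Cebpd by 3.18 without saline replicate 5, and the clock repressor Nr1d1 fell (-1.24 ± 0.35; adjusted p = 0.0511 without LPS replicate 4). Nr1d1 overlaps Thra on the other strand.

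Of 36 collagen and matrix genes 11 rose and 9 fell (camera adjusted p = 0.377), or 12 and 9 adjusted over the list alone, with a median of -0.04 (0.01 without saline replicate 5) and a mean of 0.32. The protease Adamts4, tenascin Tnc and thrombospondin Thbs1 rose by 4.57 ± 1.12, 3.41 ± 0.28 and 2.67 ± 0.60 (6.97, 3.36 and 3.24 without saline replicate 5). The protease inhibitor Timp4 fell from 48.9 ± 26.7 to 4.24 ± 1.92 CPM (-3.53 ± 0.49). Of 28 cell cycle genes 3 rose and 9 fell (camera adjusted p = 0.195), the same adjusted over the list alone. Kif23, Prc1 and Cdc20 fell (-2.46 ± 0.59, -1.46 ± 0.52 and -1.42 ± 0.40) from at most 2.07 CPM, and Cenpe rose (3.42 ± 0.56, and 4.06 without saline replicate 2). Prc1 lost its call without saline replicate 1 or 2 or LPS replicate 1, 2, 3 or 4 (adjusted p up to 0.137).

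Endothelial markers fell in 19 of 21 members, rose in 1 and fell as a list (camera adjusted p = 3.54e-07), the same counts adjusted over the list alone. With an estimated correlation the camera adjusted p was 0.503, and 0.303 without saline replicate 5. The transcription factors Sox17 and Sox18 and the secreted Egfl7 fell most, with log2 fold changes of -3.51 ± 0.43, -3.31 ± 0.91 and -3.36 ± 0.54 (SE, adjusted p = 8.52e-05, 0.0198 and 0.00117, edgeR, n = 5 per group). Among other members, chosen after their values were seen, the VEGF receptor gene Kdr, the tight junction gene Cldn5 and the cadherin gene Cdh5 fell (-3.02 ± 0.30, -1.80 ± 0.49 and -0.51 ± 0.15). Robo4, a receptor of endothelial cells, rose from 53 ± 8.16 to 130 ± 15.4 CPM (1.30 ± 0.12). Saline replicate 5 was at 7.37 CPM for Sox18, against 41 CPM or more in the other saline libraries. The log2 fold change of Sox18 was -4.01 without LPS replicate 5. The median of the list was -1.17, and between -1.45 and -1.15 under the other scalings.

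Fibroblast markers rose in 1 and fell in 5 of 16 members (camera adjusted p = 0.034, and 0.556 with an estimated correlation), or 1 and 7 adjusted over the list alone. The list did not pass without saline replicate 1, LPS replicate 2 or LPS replicate 3 (adjusted p = 0.0543, 0.0571 and 0.0972), and 9 members fell without LPS replicate 1. Thy1, Vim and Pdgfra fell (-0.97 ± 0.17, -0.81 ± 0.18 and -0.73 ± 0.14), and Ddr2 rose by 0.28 ± 0.10, a call lost without any saline replicate from 1 to 4 or LPS replicate 2, 4 or 5 (adjusted p up to 0.109). Of 13 mural cell markers, of pericytes and vascular smooth muscle, 1 rose and 5 fell (camera adjusted p = 0.14), the same adjusted over the list alone. Besides Kcnj8, the receptors Pdgfrb and Notch3 fell (-1.06 ± 0.12 and -0.69 ± 0.13), and Steap4, which the acute-phase list also holds, rose (3.13 ± 0.17).

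Of 25 monocyte and macrophage markers 5 rose and 10 fell (camera adjusted p = 0.684), or 6 and 10 adjusted over the list alone, with a median of -0.13 and a mean of 0.05. The number rising was 3 without saline replicate 1, 2 or 4 or LPS replicate 1 or 4, and the number falling was 6 without saline replicate 2 or LPS replicate 2 or 4. The chemokine receptors Cx3cr1 and Ccr2 and the growth factor receptor Csf1r fell (-4.75 ± 0.64, -1.50 ± 0.30 and -1.07 ± 0.10), and the Fc receptor Fcgr4 rose by 2.56 ± 0.77 (3.72 without saline replicate 5), a call lost without saline replicate 1, 2 or 4 or LPS replicate 1 or 4 (adjusted p up to 0.0624). The annotated interval of Cx3cr1 holds Xirp1 on the same strand, and the pair changed in opposite directions (-4.75 and 1.04). Of the 18 neutrophil markers 6 were tested, of which 3 rose and 1 fell (camera adjusted p = 0.0283, and 0.556 with an estimated correlation), or 4 and 1 adjusted over the list alone; without saline replicate 5, 7 of 8 rose, and without LPS replicate 3 or 5, 1 rose. Lrg1, also made by other cells, rose from 28.7 ± 6.84 to 222 ± 40.6 CPM, while S100a8 rose to 4.28 ± 1.98 CPM in LPS hearts (2.32 ± 0.74 on the log2 scale, and 3.79 without saline replicate 5) and Csf3r to 7.96 ± 2.15 CPM (1.76 ± 0.59, and 2.61). S100a8 and Csf3r lost their calls without most single libraries other than saline replicate 5 (adjusted p up to 0.0747 and 0.0882). Mmp9 fell (-1.21 ± 0.30).

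Of 5 tested lymphocyte markers 2 rose and 1 fell (camera adjusted p = 0.559; 2 fell without saline replicate 5), the same adjusted over the list alone. The kinase Lck and the granzyme Gzmb rose (4.76 ± 0.65 and 4.16 ± 0.63) to 9.44 ± 6.57 and 2.14 ± 1.16 CPM, and the immunoglobulin gene Ighm fell (-1.69 ± 0.24). Gzmb had 5.08 without saline replicate 2. Of 3 tested adipocyte markers Cidec rose (1.76 ± 0.58; adjusted p up to 0.0734 without saline replicate 1 or 4 or LPS replicate 2, 3 or 4) at 1.17 ± 0.53 CPM (camera adjusted p = 0.217). Without saline replicate 3 Cidec had 2.51 and 2 of the adipocyte markers rose. Of 9 atrial markers 1 rose and 2 fell (camera adjusted p = 0.629; 3 rose without saline replicate 3 and 0 without saline replicate 2 or 4 or LPS replicate 1 or 2), Tbx5 by 0.45 ± 0.15 (adjusted p up to 0.0587 without saline replicate 2, 3 or 4 or LPS replicate 1 or 2) and Gja5 and Nr2f2 downward (-2.53 ± 0.22 and -1.91 ± 0.34). Of 6 red cell and platelet markers and 3 markers of skeletal muscle and other tissues 0 passed with edgeR or DESeq2 (camera adjusted p = 0.567 and 0.607), and 1 red cell or platelet marker had an unadjusted p under 0.05. The near-identical haemoglobin genes Hba-a1 and Hba-a2 had 0.29 ± 0.25 and 0.20 ± 0.32, and Ckm and Acta1 had 0.10 ± 0.10 and 0.30 ± 0.28. Counts adjusted over these 4 lists alone were the same.

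Some calls turned on the scaling or the filter. With upper quartile scaling the rises of Traf6, Map1lc3b, Tax1bp1, Bcl2l13, Slc27a1, Cpt2, Mpc1, Pdk1, Pdha1, Ppard, Ankrd1, Mybpc3, Kcna5, Ddr2 and Tbx5 did not pass (edgeR adjusted p from 0.0565 to 0.434). With total count scaling these and the rises of Bnip3, Pnpla2, Hk2 and Atp1b1 did not pass (adjusted p from 0.07 to 0.921), while Lamp1 had a log2 fold change of -0.28 (adjusted p = 0.00904). Tfe3 passed downward under both, with -0.44 and -0.55 (adjusted p = 0.0218 and 0.0098). Becn1 passed with RLE scaling and with DESeq2 (adjusted p = 0.048 and 0.0473). Without the filter on low counts Map1lc3b, Tfec, Ankrd1, Kcna5, Atf3, Egr1, Hspa1a, Ftl1, S100a8, Csf3r and Ddr2 did not pass (adjusted p from 0.0503 to 0.0965). With limma voom Mpc1, Hspa1a and Prc1 did not pass (adjusted p = 0.0649, 0.0953 and 0.072), nor did Mpc1 with the filter of 1 CPM in 5 libraries (adjusted p = 0.0508). The tricarboxylic acid cycle list did not pass with upper quartile or total count scaling (camera adjusted p = 0.207 and 0.85), nor the ubiquitin and proteasome list with total count scaling (adjusted p = 0.293). The fetal and glucocorticoid lists passed under both scalings (adjusted p from 0.0248 to 0.0415), and the glycolysis list with RLE scaling (adjusted p = 0.0437) and with scaling without the 20 most abundant genes (adjusted p = 0.0462). Without the filter the fatty acid, glycolysis, fetal, glucocorticoid, mural and cell cycle lists passed (adjusted p = 0.0291, 0.0232, 0.043, 0.0393, 0.0331 and 0.00894). With an estimated correlation these lists had an adjusted p of at least 0.503. With genes shared between lists left out the fibroblast list did not pass (adjusted p = 0.0594) and the mural list did (adjusted p = 0.00938).

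**Figure D3:**
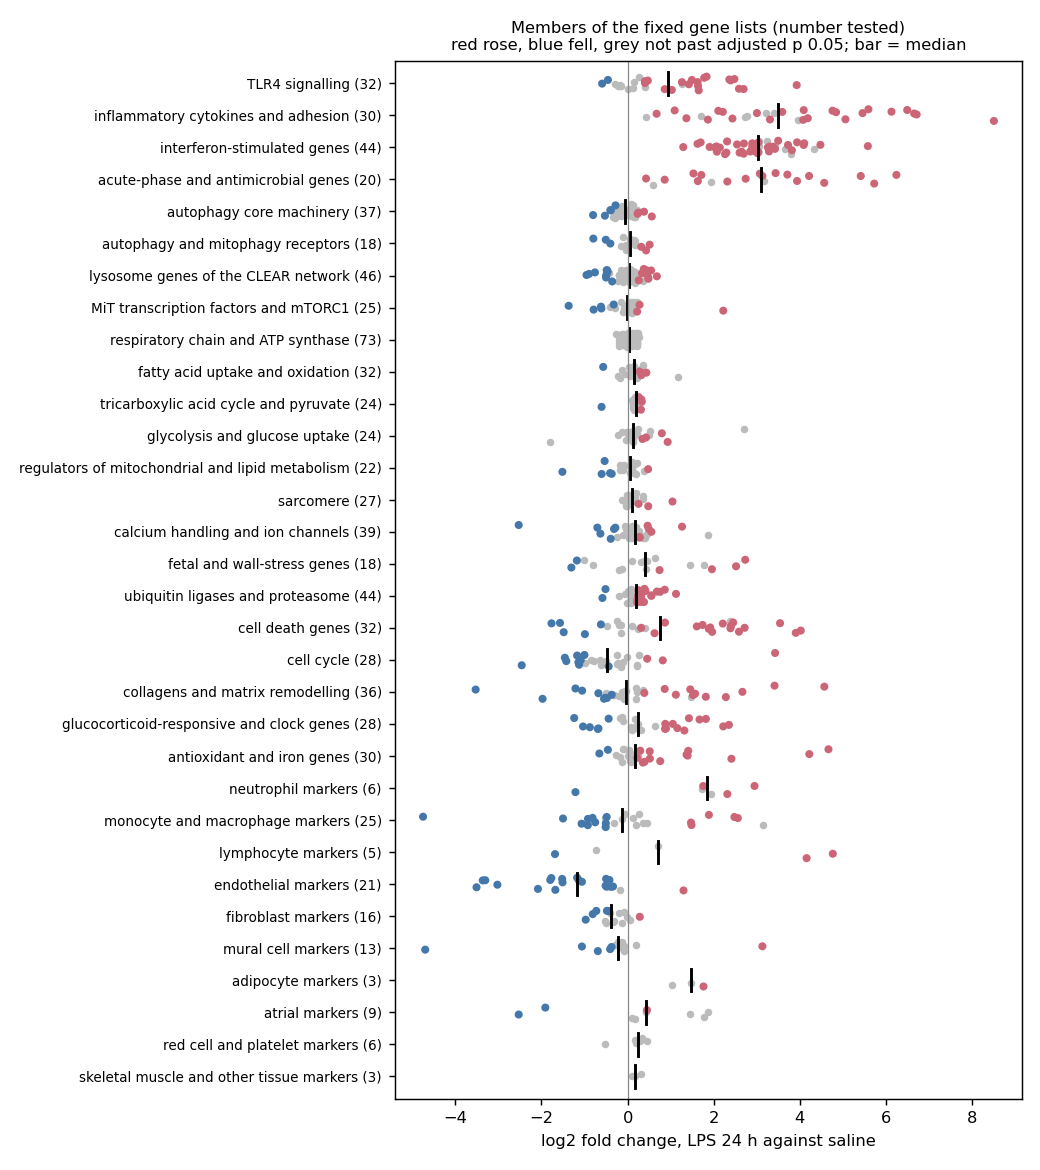
Log2 fold change of LPS against saline (horizontal axis) of each tested member (points) of the 32 fixed gene lists (rows, with the number tested); red points rose, blue points fell, grey points did not pass adjusted p 0.05, and black bars are medians. The interferon list had a median of 3.03 (4.37 without saline replicate 5), the endothelial list -1.17 and the respiratory chain list 0.04 (-0.23 with total count scaling).

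The authors' deposited tables were set beside these calls, as no independent evidence since they were made from the same libraries. All 6271 genes of the larger deposited FPKM table were among the 6359 genes called by DESeq2, and 5303 of them were called by edgeR. Of the 40 genes in the authors' deposited TLR4 pathway table, 35 were tested, 16 rose and 4 fell, and 16 of the 40 were in the TLR4 list fixed here. The 4 that fell were Ikbip, Mkks, Tab1 and Tram1, of which only Tab1 is in the fixed list. In the authors' deposited table of 1016 Reactome terms, 80 terms had an adjusted p under 0.05. The first was cytokine signalling in the immune system, with 184 differential genes (148 up and 36 down, adjusted p = 6.93e-07), and the TLR4 cascade had 65 (44 up and 21 down, adjusted p = 0.000111). In the authors' deposited table macroautophagy had 18 differential genes of 65 (10 up and 8 down, p = 0.953) and respiratory electron transport 5 of 61 (5 up).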

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

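The tests of saline replicate 5 and of the endothelial markers were chosen after the results were seen. Those of the zinc finger genes and of other splits of the libraries were written down before their own results. In 49 of 268 groups of 5 libraries, the highest or lowest library lay apart from the others by more than Dixon's 95% critical value. For independent, normally distributed values about 1 in 20 groups exceed it. Many of the groups are genes that change together, and in some only 1 library was above 0, so the 49 cannot be set against that rate. Saline replicate 5 was the high library in 33 of the 49 groups and the low library in 4.

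Saline replicate 5 lay between the groups, at -0.563 on the first component where the next saline library was at -55.1, and 1.04% of its counts came from interferon-stimulated genes against at most 0.205% in the other saline libraries. In genes of at least 10 CPM in a group that changed at least 4-fold without it, its CPM lay a median share of 0.291 of the way from saline replicates 1 to 4 to the LPS mean in 490 rising genes and 0.636 in 145 falling genes. RNA of these LPS hearts mixed in at 1 share would put it at equal shares in both, but the falling genes lay further along by at least 0.235 over 20 choices of single libraries as references, so that explanation is argued against, while material from outside the series stays open. A wrongly labelled heart that responded as these 5 LPS hearts did is argued against too. Saline replicate 5 lay inside the LPS range in 3.94% of those genes. An LPS library lay inside the range of the others in 46.5% to 78.1%. The range test cannot speak to a wrongly labelled LPS heart with a weaker response, since that would lie outside the range as well. Saline replicate 5 lay inside the range of saline replicates 1 to 4 in 4.57% of those genes. Each of these saline libraries lay inside the range of the others in at least 33.1%. The library thus matched neither group, and the range test does not bear out its saline label either. The design gives no biological difference for this library, so no biological explanation was tested.

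In CPM, saline replicate 5 was the high saline library for Traf6 (28.2), Cxcl5 (2.02), Gm37975 (0.713), Ubd (0.475), Gm10851 (1.66), Tnfaip3 (123), Myd88 (55.2), Irak3 (21), Csf3 (5.17), Il6 (11), Cxcl11 (11.5), Cxcl9 (268), Dhx58 (20.7), Ptx3 (64.7), Lcn2 (26.1) and Saa3 (12.7). It was also high for Lamp2 (236), Tfec (4.99), Pnpla2 (316), Pdk1 (183), Atf3 (64.2), Bcl2a1a (1.13), Mlkl (16.6), Casp4 (48.9), Adamts4 (30.3), Cebpd (166), Slc7a11 (0.891), Hamp (1.43), S100a8 (3.15), Csf3r (6.65) and Ddr2 (56.3). It was the low saline library for Kif26a (6.30), Cpt1a (44.9), Rxra (53.4) and Sox18 (7.37). Of the other saline libraries, replicate 4 was high for Csf2 (0.174 CPM, the only saline library above 0), replicate 1 was high for Ppargc1b (24.4 CPM) and replicate 2 was low for Ckm (1010 CPM). Among LPS libraries, replicate 3 was low for Gm37975 (10.8 CPM) and Fbxo32 (168 CPM) and high for Pnpla2 (441 CPM) and in total count (1.7e+07). LPS replicate 1 was high for Bcl2a1a (6.85 CPM) and Egfl7 (12 CPM), LPS replicate 5 was low for Vmp1 (53.6 CPM) and high for Pdgfra (53 CPM), and LPS replicate 4 was high for Hba-a2 (60.6 CPM).

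Endothelial markers fell in 19 of 21 members, but by very different amounts, from -3.51 to 1.30 on the log2 scale. A smaller share of endothelial RNA would lower all of them by 1 factor, if endothelial cells alone made them and all made them evenly. Their SD of 1.22 was 8.41 times their median SE of 0.15, so a common factor alone is argued against. Uneven loss among endothelial cells, or markers made by other cells too, could also give unequal falls, and the spread cannot tell these apart. A change of expression within endothelial cells, with or without some loss of these cells, is a candidate explanation that bulk RNA could not separate further.

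C2H2 zinc finger genes, as the deposited family column gives them, fell in 177 and rose in 29 of 407 protein-coding members, with a median log2 fold change of -0.49 (camera adjusted p = 1.95e-06 over 43 families looked at after the data were seen, and adjusted p = 0.655 with an estimated correlation). With saline replicate 5 left out, 192 fell and 34 rose, and the median was between -0.77 and -0.47 under the other scalings. Medians of 10000 random lists averaged -0.16 (95% between -0.22 and -0.10) when matched on expression, -0.03 (-0.08 to 0.03) on gene length and 0.00 (-0.05 to 0.05) on GC content, so none of these 3 alone accounts for the fall. Reads shared between near-identical members stay open, since the counting is not given in the sources used here. A common lowering of these transcripts in LPS hearts therefore stays a hypothesis.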

How the results depend on the processing

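The fits without saline replicates 2 and 5 together, and with an estimated correlation without saline replicate 5, were chosen after the results were seen; all other alternatives were fixed before the data were examined. Of 127 named genes, 75 kept direction and side of the threshold in all 21 settings, Tlr4 and Tfeb among them; over all genes and settings 211 calls were lost, 9 gained and 2 reversed, and 25 values past the threshold neither before nor after changed sign. Under total count scaling Map1lc3b had -0.03 and Mybpc3 -0.02. This scaling sets no factor for composition and shifts the median log2 fold change of all genes by -0.27, so 1711 genes rose and 5774 fell, 1724 of them at least 2-fold; with upper quartile scaling 4407 fell. At adjusted p under 0.01, 1930 fell and 1 list passed downward, as the stricter threshold alone brings. Between 4785 and 6208 genes differed with 1 library left out, and 1 to 2 lists passed downward. Downward lists were 4 without the filter, and the cause was not tested. With an estimated correlation 0 lists passed upward and 0 downward, and without saline replicate 5 as well 3 and 0. The correlation is then taken from the spread between libraries, where saline replicate 5 moves whole lists. With all libraries it ranged from -0.0411 (skeletal muscle and other tissue markers) to 0.929 (interferon list), against the preset 0.01. Saline replicate 5 alone does not account for the lost lists. Without it the interferon, endothelial and cell death lists still had camera adjusted p = 0.303 with an estimated correlation. Of the list results, 673 stayed on their side of the threshold, 32 lost and 29 gained a call. The first component held 76.6% of the variance of all tested genes. On the second, with 5.29%, LPS replicates 1 and 5 lay at -34.8 and 38.2, and the other libraries between -5.83 and 6.81. No pairing of the samples by replicate number was detected: correlations of same-numbered libraries were -0.03, -0.07, 0.18, 0.02 and -0.05, and 1 of 5 saline libraries correlated best with its own number. With the replicate block 5418 genes differed. Ddit4, Slc27a1, Mpc1, Ankrd1, Mybpc3, Egr1, Angptl4, Nr1d1, Fcgr4 and Sox18 did not pass then (adjusted p from 0.0541 to 0.129), nor did the neutrophil list (0.0703), and Hba-a1 passed (0.0338). Camera was not run on DESeq2 values, and limma voom values are already its scale. Of simulated changes of 2-fold, 12 of 27 were recovered among genes with a mean count below the median and 21 of 23 above it; at 1.5-fold these were 3 of 24 and 8 of 26. In this simulation changes of this size were missed more often in genes of low count. Far fewer genes were changed in it than in the data, which makes the adjusted threshold stricter, and depth was not varied.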

Other observations

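The gene families below were looked at after the data were seen, 43 in all, and all their tests were chosen then; genes named for them were chosen after their values were seen. Apart from families of the deposited transcription factor column, members were taken by patterns in gene symbols. A family can thus hold genes of another function that share a symbol prefix. In LPS hearts, members of several families rose or fell. Of members that passed, Ddx58 (helicases) also belongs to the fixed interferon list, Serpina3n (serpins) to the acute-phase list and Notch3 (Notch) to the mural list. Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, rose in 8 and fell in 0 of 17 members (camera adjusted p = 7.26e-04, and adjusted p = 0.627 with an estimated correlation; median 0.27, and 0.00 with total count scaling). RNA helicases and ribosome assembly factors rose in 22 and fell in 2 of 61 (camera adjusted p = 0.0130, and 0.694 with an estimated correlation, median 0.19, and -0.09 with total count scaling). Genes with symbols of translation initiation factors rose in 19 and fell in 3 of 53 (camera adjusted p = 0.0158, and 0.694 with an estimated correlation, median 0.20, and -0.07 with total count scaling). Genes with symbols of cytosolic ribosomal proteins rose in 4 and fell in 6 of 93 (camera adjusted p = 0.612). Both counts rest on symbols alone. Serpins, inhibitors of proteases, rose in 12 and fell in 2 of 19 (adjusted p = 7.26e-04, and 0.627 with an estimated correlation), and H2 histocompatibility genes, which present antigens, rose in 10 and fell in 2 of 16 (adjusted p = 0.0357, and 0.694 with an estimated correlation). Reads of near-identical serpin and H2 genes cannot be told apart.

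Notch receptors, ligands and targets fell in 8 and rose in 2 of 13 (camera adjusted p = 0.0351, and adjusted p = 0.661 with an estimated correlation), and Eph receptors and ephrins fell in 7 and rose in 0 of 15 (adjusted p = 0.0279, and 0.627 with an estimated correlation). The Notch target genes Hey1 and Heyl fell (-3.63 ± 0.53 and -3.61 ± 0.34, log2 fold change and SE), the ligands Jag2 and Dll4 fell (-2.14 ± 0.23 and -1.69 ± 0.41) and the ligand Dll1 rose (1.71 ± 0.23). Efnb2, an ephrin of arterial endothelium, and its receptor Ephb4 fell (-2.26 ± 0.28 and -1.78 ± 0.15). Of 3 tested genes of soluble guanylate cyclase, the nitric oxide receptor, Gucy1a1 and Gucy1b1 fell (-2.77 ± 0.15 and -2.37 ± 0.16), and Gucy1a2 had -0.43 ± 0.29 (adjusted p = 0.265). These changes stood beside falls of 19 of 21 endothelial markers (median -1.17) and 5 of 13 mural markers in the same hearts. Hey1, Heyl, Jag2, Dll4, Dll1, Efnb2, Ephb4, Gucy1a1 and Gucy1b1 kept their call with any 1 library left out. With an estimated correlation 0 of 43 families passed (adjusted p of at least 0.627), so the families are groups of changed genes rather than tested themes.

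Of the other 99 splits drawn from 126 into 5 and 5 libraries, the highest gave 643 genes, with saline replicate 5 exchanged for LPS replicate 3, and the median gave 0. The real split gave 5533, so 1 of 100 splits, the real one itself, gave as many. Every other split mixed LPS and saline hearts, so the difference between the groups widened the spread within its sides and lowered its count. Low counts there were largely built in, and the splits cannot exclude chance as a source of the difference. In the authors' deposited TLR4 pathway table, 7 of 40 genes are described as subunits of the AP-1 adaptor complex of vesicle transport and 2 as translocating chain-associating membrane proteins. Il6 had 1 read in saline replicates 1 to 4, so its ratio of LPS to these libraries was 15500 with a 95% counting interval of 2780 to 613000. The ratio was 3910 (1080 to 32300) for Saa3, from 2 reads.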
